A study of Mus musculus with 8 samples.

How the data were processed

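The data are single-cell RNA sequencing libraries of the dorsal upper back of mouse embryos, made with the 10x Genomics single cell 3' v3 kit per the labels. There were 8 libraries from 6 stages and 3 sorts, each a group of its own with 1 library, so no comparison has a replicate. Per the labels, head and limbs were removed, the tissue was digested with either trypsin or collagenase and dispase, and live cells were sorted. Which enzyme a library received is not stated. The counts are UMI counts per gene and barcode as deposited, made by the authors with Cell Ranger and the mm10 genome per the processing notes, with no normalisation. Per the file headers the Cell Ranger version was 3.0.1 for the Ebf2-GFP libraries and 3.1.0 for the others. The barcode lists and gene lists deposited with them hold names, not measurements, and whether the barcodes had been filtered is not stated. The Ebf2-GFP matrices had 31054 rows, 1 of them eGFP, and the others 31053. The E10.5 library was deposited without a gene list, so its genes were not analysed here. It entered no comparison of classes or genes, only a test of its row order.

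The filters, the clustering settings, the markers, the gene lists, the rule for genes and the settings varied first were fixed before the data were examined, and exceptions are stated. Barcodes with at least 1000 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored in each library by the share of simulated doublets among a barcode's nearest neighbours. The top-scoring barcodes were removed, which was 662 to 998 per library. Their share of the scored barcodes was 0.8% for each 1000 barcodes that the library held before the filters. Counts of the 7 libraries with gene names were log-normalised and clustered together without integration, on 2000 variable genes chosen by their mean rank within libraries, 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1.0 with seed 7. Fixed-list, sex-linked, mitochondrial and ribosomal protein genes were kept out of the clustering. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

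Clusters were named "-like" by fixed markers of 18 cell classes. The thresholds for a name were set after the data were seen: at least 3 markers of the class with a UMI in 10% of cells and 2-fold over the other cells, and either 1 of them among the 10 leading genes or at least 50% of the class's markers. The class with the most markers among the leading genes took the name, and clusters led by genes of hepatocytes, cardiac cells or the inner ear stayed unnamed. A like rule for shallow clusters left no cluster unnamed at resolutions 1.0 and 2.0. Of the clusters with at least 3 markers of a class, 6 stayed without a name: clusters 41 and 42 for leading genes of cardiac cells and hepatocytes, and clusters 12, 18, 36 and 40 for the need for a leading gene or for 50% of the markers. They held 1.70% of cells at E11.5, 8.71% at E12.5, 7.69% at E13.5, 5.64% and 4.90% in the E14.5 and E15.5 PDGFRa libraries, and 6.31% and 5.64% in the E14.5 and E15.5 Ebf2-GFP libraries. For the adipogenic class these were clusters 18 and 42, with 0.156%, 0.630%, 0.117%, 0.777% and 2.92% of cells in the same order, and 4.72% and 5.17% in the Ebf2-GFP libraries. For the fibroblast class they were 4 clusters, with 1.47%, 7.70%, 7.61%, 5.57% and 4.89%, and 6.04% and 5.57%. For the myogenic class it was 1 cluster, with at most 0.386%. Cluster 16, named adipogenic-like with Pparg among its leading genes, had 4 of 10 adipogenic and 5 of 10 fibroblast markers. Cluster 28 had 10 of 10 adipogenic markers and a median depth 2.96 times that of the other cells. Doublets were weighed for it and it was kept: its cells had passed the removal of doublets, and against cluster 16 of the E15.5 Ebf2-GFP library its extracellular matrix genes had a median log2 ratio of −4.30 and Pdgfra stood at 3.91 against 128 CPM, while a doublet with a mesenchymal cell would carry both. Doublets of 2 cells of cluster 28 are not excluded by this. No cluster met the dermomyotome markers at resolution 1.0, and dermomyotome-like cells were taken from resolution 2.0 after seeing this.

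UMIs were summed over the cells of a class in a library and given as CPM of that sum. A gene was past the rule with at least 100 UMIs over the 2 sums, at least 20 CPM in the higher, and a 2-fold difference whose exact conditional 95% interval excluded 1. At least 50 cells of the class were needed in each library. No test between groups was run and no p-values are given. Ratios against 0 counts used a floor of 3 counts. The genes named were the 12 largest folds in each direction, with the E14.5 level in between over 3 stages and the rule met at both stages over 2 sorts, ranked there by the smaller fold. From E13.5 to E15.5, the counts of genes and list members past the rule needed the E14.5 level in between as well. Marker, haemoglobin, mitochondrial, ribosomal protein, sex-linked, Gm and Rik genes were not named. Some genes that the rule would name are not reported here. Members of 14 fixed lists were given as counts with examples: GATA and EBF family factors, adipogenic and brown fat regulators, thermogenic and mitochondrial genes, lipid storage and synthesis genes, preadipocyte genes, WNT target genes, BMP pathway genes, hedgehog target genes, retinoic acid pathway genes, extracellular matrix genes, cell cycle genes, Hox genes, dissociation stress genes and sort genes. List medians have intervals from 1000 Poisson redraws of the counts, and percentiles among 10000 random lists matched on mean CPM. Genes that changed 2-fold the same way in at least 50% of the other classes with 30 UMIs were counted, a step added after seeing that some genes changed in every class. For shares of cells with a UMI, cells were also thinned to 5000 UMIs and shallower cells left out.

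The rule was tested on simulated Poisson sums of equal expected size, drawn from the profile of a single library, in which 200 genes were changed. This is the counting error that the intervals assume. Variation between cells or between libraries was not simulated, so the shares below do not cover it. With sums the size of the adipogenic-like cells, 5134 genes were tested, 94.5% of intervals held the true value, no unchanged gene was called, and 0% of genes raised 1.5-fold, 94% of those raised 2.5-fold and 100% of those raised or lowered 4-fold were called. With sums the size of the fibroblast-like cells, 11404 genes were tested, 95% of intervals held the true value, no unchanged gene was called, and 0%, 96% and 100% of genes raised 1.5-fold, 2.5-fold and 4-fold were called, but only 62% of those lowered 4-fold.

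The E15.5 against E13.5 comparisons planned for adipogenic-like cells, of the thermogenic list and of genes past the rule, were not possible with 13 such cells at E13.5, and E15.5 was set against E14.5 in their place. Settings varied were no removal of doublets, at least 2000 genes with at most 5% mitochondrial UMIs, Leiden resolutions 0.5 and 2.0, 4000 variable genes, each library clustered on its own, median-of-ratios scaling, at least 30 UMIs, and cells thinned to 5000 UMIs. Settings added after the data were seen were at most 20% mitochondrial UMIs, clusters 16, 28 and 3 each on its own, and leaving out genes changed in other classes.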

Results

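Single-cell RNA sequencing was applied to cells of the dorsal upper back of mouse embryos at 6 stages from E10.5 to E15.5. This region holds the dermomyotome, the part of the somite that gives rise to muscle, dermis and brown fat, and the mesenchyme around it. The cells had been sorted in 3 ways, and each of the 8 libraries formed a group of its own, with no replicate. The Ebf2-GFP libraries (E10.5, E14.5 and E15.5) came from embryos with a GFP reporter of Ebf2, a transcription factor of brown preadipocytes, and were mixed from 75% GFP-positive and 25% GFP-negative cells. The PDGFRa libraries (E13.5, E14.5 and E15.5) were mixed from 75% of cells positive and 25% negative for PDGFRa, a receptor of mesenchymal progenitors. The E11.5 and E12.5 libraries (PDGFRa/LRIG1) were mixed from 30% PDGFRa-positive LRIG1-negative, 25% PDGFRa-negative LRIG1-positive, 30% double-positive and 15% double-negative cells.

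The libraries held 9795 to 12333 barcodes and 102680568 to 165477371 UMIs. The median barcode had 14796 UMIs in the E10.5 library, 12821 at E11.5, 11944 at E12.5, 9374 at E13.5, 9513 and 11604.5 in the E14.5 and E15.5 PDGFRa libraries, and 7297.5 and 8833 in the E14.5 and E15.5 Ebf2-GFP libraries. The E10.5 library was read without a gene list and is described here by its depth, 153273488 UMIs over 10029 barcodes, and by a test of its row order. Of the other 7 libraries, 7231 to 9400 cells per library passed the filters and the removal of doublets. The E15.5 Ebf2-GFP library lost the most barcodes to the filters, with 71.5% passing, against 80.8% to 86.9% in the other 6. Each comparison sets libraries, not replicated conditions, against each other. Brackets give 95% intervals that cover counting error only: exact binomial (Clopper-Pearson) for shares, exact Poisson for UMI sums and their ratios, and redrawn counts for list medians. Mouse genotype and Cell Ranger version changed together with the sort. The labels list 2 sequencers for each Ebf2-GFP library, do not say which was used for the others, and do not give the digestion enzyme of each library, so a difference between sorts cannot be assigned to any of these.

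Clustering of the 7 libraries together gave cells of 15 named classes, whose shares followed stage and sort. At E11.5 the largest named classes were neural-like (1918 of 8985 cells) and sclerotome-like (1744 cells), the latter being the somite part that forms the axial skeleton. At E15.5 in the PDGFRa library they were fibroblast-like (2012 of 7837 cells), myogenic-like (984 cells), chondrocyte-like (886 cells) and tendon-like (579 cells). From E13.5 to E15.5 in the PDGFRa sort, the tendon-like share was 13.4-fold higher (log2 3.74), the mural-like share 3.11-fold (1.64) and the myogenic-like share 1.81-fold (0.85), while log2 values were −4.64 for sclerotome-like, −3.94 for erythroid-like and −3.28 for neural-like cells. These shares can be set by the sort mix and by depth, which differed between libraries as given above.

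The Ebf2-GFP and PDGFRa libraries of the same stage differed in most classes. At E14.5 and E15.5, log2 ratios of Ebf2-GFP over PDGFRa shares were 3.14 and 4.63 for keratinocyte-like, 3.70 and 3.38 for lung epithelial-like, 1.47 and 4.02 for neural-like, 1.69 and 1.42 for mural-like, and 1.15 and 1.29 for macrophage and leukocyte-like cells. They were −1.42 and −3.72 for chondrocyte-like, −1.51 and −1.81 for endothelial-like, −1.03 and −1.88 for Schwann and neural crest-like, −1.66 and −2.84 for mesothelial-like, and −0.27 and −1.08 for myogenic-like cells. The fibroblast-like shares lay close together (0.23 and 0.14), but those of its clusters did not: in the PDGFRa and Ebf2-GFP libraries, cluster 3 held 1461 and 452 cells at E14.5 and 556 and 139 at E15.5, and cluster 4 held 172 and 1565 cells at E14.5 and 935 and 1748 at E15.5. The tendon-like ratio was 0.90 at E14.5 and −1.15 at E15.5. At Leiden resolution 1.0 no cluster took the name osteogenic-like or melanoblast-like, although cluster 14, named chondrocyte-like, met 3 of 6 osteogenic markers and cluster 34, named Schwann and neural crest-like, met 5 of 6 melanoblast markers. At resolution 2.0 a cluster of 2422 cells was osteogenic-like. Clusters without a name held 46.0% of cells at E11.5, 43.4% at E12.5, 47.9% at E13.5, 39.5% and 28.9% in the E14.5 and E15.5 PDGFRa libraries, and 22.3% and 11.1% in the E14.5 and E15.5 Ebf2-GFP libraries.

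Adipogenic-like cells, named by genes of fat cell identity such as Pparg, Cebpa, Fabp4, Adipoq and Plin1, were found from E13.5 in this clustering and were more frequent in the Ebf2-GFP libraries. None were found among 8985 cells at E11.5 or 7782 cells at E12.5, which allows shares of up to 0.0334% and 0.0386%. In the PDGFRa sort the share was 0.152% [0.0812, 0.261] at E13.5 (13 cells), 1.33% [1.11, 1.58] at E14.5 (125 cells) and 2.91% [2.55, 3.31] at E15.5 (228 cells), a 19.1-fold difference from E13.5 to E15.5 (log2 4.25 [3.45, 5.19]). In the Ebf2-GFP sort it was 5.42% [4.97, 5.90] at E14.5 (499 cells) and 15.1% [14.30, 15.96] at E15.5 (1093 cells). The Ebf2-GFP share was thus 4.08-fold that of the PDGFRa library at E14.5 (log2 2.03 [1.74, 2.32]) and 5.20-fold at E15.5 (2.38 [2.17, 2.59]). The stage of first finding depended on the settings: no such cell was found at E13.5 at Leiden resolution 0.5, with each library clustered on its own, or with at most 20% mitochondrial UMIs, a limit chosen after the data were seen, and the last 2 left none in the E14.5 PDGFRa library either. With at least 2000 genes and at most 5% mitochondrial UMIs the log2 ratio from E13.5 to E15.5 was 0.77 [0.43, 1.11].

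**Figure D1:**
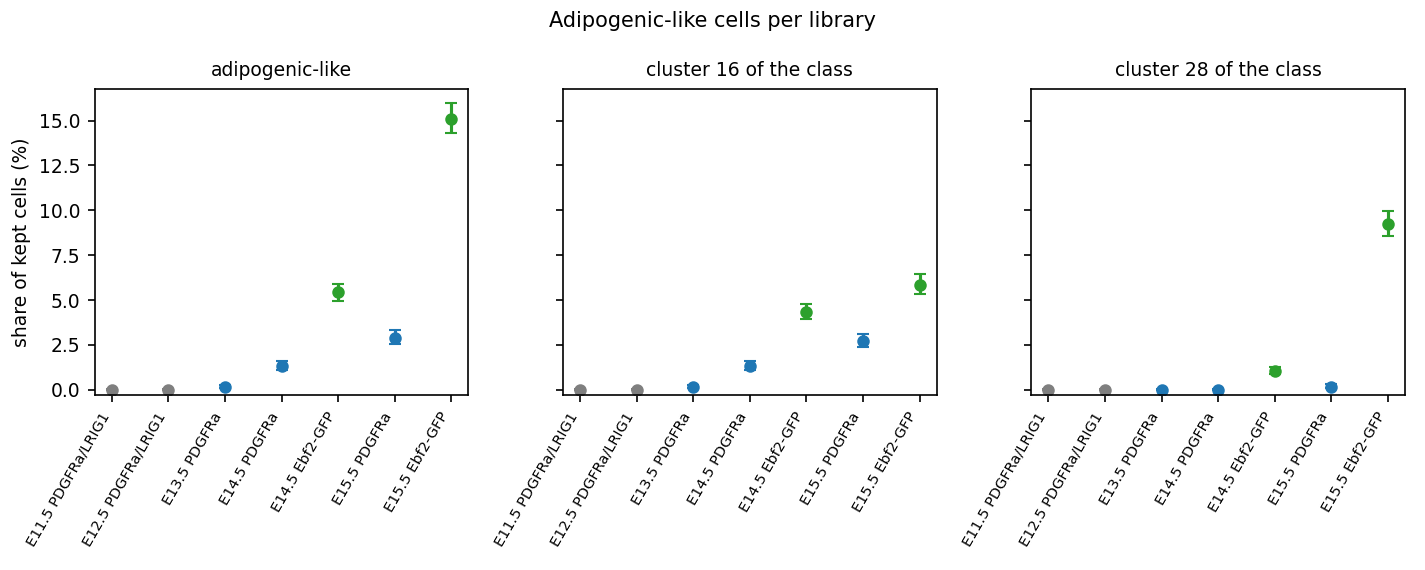
Share of adipogenic-like cells, and of each of their clusters 16 and 28, in percent of the cells kept in each of the 7 libraries with gene names (points), with exact 95% binomial intervals (bars). The share of the class is 0 at E11.5 and E12.5 and highest in the E15.5 Ebf2-GFP library, at 15.1%.

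The class held 2 clusters that the sorts did not share evenly. Cluster 16, led by genes such as Cxcl13, Ccl11, Agt, Pparg and Gsn, had 125 and 214 cells in the E14.5 and E15.5 PDGFRa libraries and 401 and 424 in the Ebf2-GFP libraries, so that the Ebf2-GFP share was 3.28-fold (log2 1.71 [1.42, 2.01]) and 2.15-fold (1.10 [0.86, 1.35]) higher. Cluster 28, led by Car3, Fabp4, Adipoq, Gpd1, G0s2 and Plin1, genes of lipid-storing fat cells, had 98 and 669 cells in the Ebf2-GFP libraries and 0 and 14 in the PDGFRa libraries. Its share was 33.4-fold higher in the Ebf2-GFP library at E14.5 (lower limit 26.6), with the count of 0 set to 3 cells, and 51.8-fold at E15.5. From E14.5 to E15.5 in the Ebf2-GFP sort, the cluster 28 share was 8.69-fold higher (3.12 [2.81, 3.44]) and the cluster 16 share 1.35-fold higher (0.43 [0.23, 0.63]). Pdgfra, the gene of the PDGFRa gate, stood at 3.91 CPM in cluster 28 and 128 CPM in cluster 16 of the E15.5 Ebf2-GFP library. The size of the share ratios depended on the settings: with at least 2000 genes and at most 5% mitochondrial UMIs per cell the log2 ratios between sorts were 1.19 and 1.21, and at Leiden resolution 0.5 they were 6.72 and 4.25.

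Gata6, the transcription factor named in the series title (ENSMUSG00000005836, GRCm38 chromosome 18, 11052064 to 11085635, plus strand), was higher in adipogenic-like than in fibroblast-like cells of the E14.5 PDGFRa library. It stood at 54.3 CPM [42.3, 68.6] in adipogenic-like cells (70 UMIs) and 15.1 CPM [13.3, 17.0] in fibroblast-like cells (266 UMIs), a 3.61-fold difference (log2 1.85 [1.45, 2.24]). The ratio was 2.49 [2.22, 2.75] in the E15.5 PDGFRa library, 1.27 [1.08, 1.45] in the E14.5 Ebf2-GFP library and 0.50 [0.33, 0.68] in the E15.5 Ebf2-GFP library. The fibroblast-like cells were mostly of cluster 3 in the E14.5 PDGFRa library (1461 of 1901) and mostly of cluster 4 in the Ebf2-GFP libraries (1565 of 2186 and 1748 of 2040). Cluster 16 alone had 54.3, 70.0, 88.4 and 82.0 CPM in these 4 libraries, in that order, with ratios of 1.85, 2.60, 1.56 and 1.74. Cluster 28 had less Gata6, 39.9 CPM at E14.5 and 23.0 CPM at E15.5 in the Ebf2-GFP libraries, with log2 ratios to cluster 16 of −1.15 [−1.51, −0.80] and −1.83 [−2.04, −1.62].

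Outside these classes, Gata6 was highest in mesothelial-like cells (179.7 CPM at E11.5) and in the unnamed cluster 40 (340.2 CPM at E11.5), whose leading genes include Tbx20, Gata4 and Gata6. The share of adipogenic-like cells with a Gata6 UMI was 40.0% at E14.5 and 49.1% at E15.5 in the PDGFRa libraries, and 46.5% and 42.8% in the Ebf2-GFP libraries. The median depths of these cells were 9581, 13943, 10525 and 21084 UMIs. In neural-like cells, which should lack the gene, the shares were 0.1996%, 0, 0.661% and 0.376%, at median depths of 6852, 8401, 5449 and 5128 UMIs. With each cell thinned to 5000 UMIs, the adipogenic-like shares were 21.7%, 23.0%, 27.0% and 19.4%, leaving out 10, 19, 59 and 28 shallower cells, and the neural-like shares were 0.233%, 0, 0.690% and 0.180%, leaving out 71, 5, 493 and 506 cells. The difference in the E14.5 PDGFRa library turned to −0.12 [−0.58, 0.31] with at least 2000 genes and at most 5% mitochondrial UMIs, which changes both the cells kept and the clusters. At resolution 2.0 the adipogenic-like clusters 38 and 30 held 38 and 0 cells of this library, too few for a value. Cxcl13, Ccl11 and Gata6 were then leading genes of cluster 19, named mural-like, with 222 cells of this library. The ratio of the E15.5 Ebf2-GFP library turned negative under 7 of 11 alternatives, such as removing no doublets (−0.39) and Leiden resolution 0.5 (−0.48), and that of the E14.5 Ebf2-GFP library under 2 of 11. In the E15.5 PDGFRa library it stayed positive under all 8 alternatives that gave a value, from 0.16 to 2.60.

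**Figure D2:**
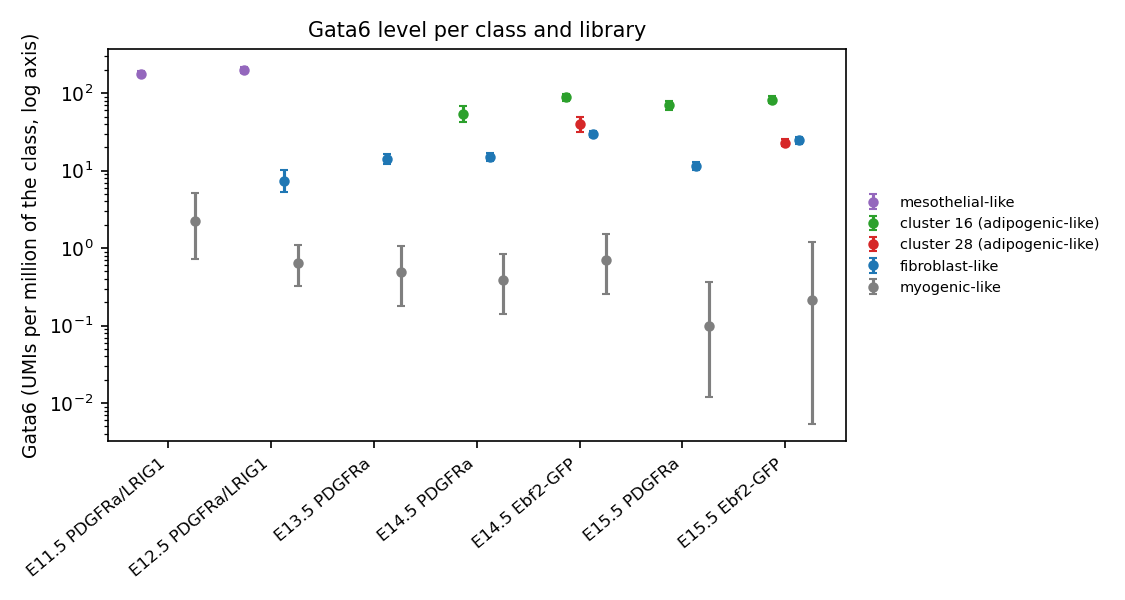
Gata6 in CPM (log axis) in the summed cells of 3 classes and of clusters 16 and 28 in each library with at least 50 of them (points), with exact 95% Poisson intervals (bars). Cluster 16 lies between 54.3 and 88.4 CPM in the E14.5 and E15.5 libraries, above the fibroblast-like cells of the same library, which reach 29.9 CPM.

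The E14.5 PDGFRa library, where adipogenic-like cells were all in cluster 16, also set WNT and other signalling genes apart from fibroblast-like cells. Of the genes measured, 111 were higher and 284 lower in adipogenic-like cells by the rule of at least 2-fold. WNT target genes had a median log2 ratio of −2.41 [−2.73, −1.92], with 7 of 13 lower, and a percentile of 0 among 10000 random lists of like expression. BMP pathway genes stood at −1.02 [−1.28, −0.76], with 5 of 13 lower. GATA and EBF family factors stood at 0.72 [0.57, 1.00] (percentile 99.99), with 2 of 5 higher: Gata6, and Ebf2 at 95.4 against 34.9 CPM (1.45 [1.16, 1.73]). Thermogenic genes (0.16) and lipid storage genes (0.00) had no member past the rule. Against the fibroblast-like cells, the WNT median was −2.26 in the E14.5 Ebf2-GFP library, −2.59 in the E15.5 PDGFRa library and −2.89 in the E15.5 Ebf2-GFP library.

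The matched stages E14.5 and E15.5 allow the adipogenic-like cells of the 2 sorts to be compared. Genes of lipid storage were higher in Ebf2-GFP cells at both stages, and genes of the retinoic acid pathway were lower. By the rule, 159 genes rose and 221 fell in Ebf2-GFP against PDGFRa at both stages. The counts were 71 and 43 with at least 2000 genes and at most 5% mitochondrial UMIs, 81 and 103 with 4000 variable genes and 63 and 81 with cells thinned to 5000 UMIs. Most adipogenic-like cells of the E15.5 Ebf2-GFP library belonged to cluster 28 (669 of 1093), and most of the other 3 libraries to cluster 16 (125 of 125, 401 of 499 and 214 of 228), so the class held different clusters. The median of all genes stood at −0.05 at E14.5 and −0.24 at E15.5.

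Of the lipid storage and synthesis genes, 9 of 16 measured rose at both stages and none fell, with medians of 1.57 [1.25, 2.26] at E14.5 and 2.18 [1.93, 2.47] at E15.5, both at percentile 100. Examples are Car3 (8.65 and 4.04), Mrap (5.35 and 5.34) and G0s2, an inhibitor of lipolysis (2.96 and 4.26). Gpd1, the glycerol-3-phosphate dehydrogenase of triglyceride synthesis, stood at 4.48, with 0 UMIs in the E14.5 PDGFRa library set to 3, and 5.05. All 4 are leading genes of cluster 28. No gene of the fixed lists was used to cluster, but the class was named by fat cell genes and cluster 28 was held mostly by the Ebf2-GFP libraries. These rises are thus not independent of the name and the cluster mix. Of the thermogenic and mitochondrial genes, 1 of 6 rose at both stages (Idh3a, 1.12 and 2.48), with medians of 0.85 [0.57, 1.10] (percentile 98.8) and 2.24 [2.04, 2.55] (percentile 100), which were 0.25 and −0.10 [−0.28, 0.14] with at least 2000 genes and at most 5% mitochondrial UMIs. Of the adipogenic and brown fat regulators, 2 of 12 rose: Ppargc1b, a coactivator of mitochondrial genes (2.80 and 3.06), and Srebf1 (1.76 and 2.16). Of the cell cycle genes, 8 of 16 rose and 1 fell, among them Ccnb1 (3.03 and 2.98), Ccna2 (3.03 and 2.20), Mki67 (2.83 and 2.32) and Top2a (2.63 and 2.35). Their medians of 1.31 and 1.49 turned to −0.25 at E14.5 with at least 2000 genes and at most 5% mitochondrial UMIs and to −0.20 at E15.5 with 4000 variable genes.

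Of the retinoic acid pathway genes, 3 of 5 fell, such as Crabp2, a carrier of retinoic acid (−2.20 and −4.77), and Aldh1a2, which makes it (−1.12 and −2.62). Of the BMP pathway genes, 2 of 7 fell, Smad7 (−2.09 and −2.67) and Id3 (−1.11 and −2.31). Of the preadipocyte genes, Cd24a (−1.57 and −2.41) and Sfrp2 (−1.22 and −2.84) fell and Col15a1, a leading gene of cluster 16, rose (4.55 and 1.17), of 8 measured. None of the 19 extracellular matrix genes, 4 GATA and EBF family factors, 4 Hox genes, 3 hedgehog target genes, 2 WNT target genes and 3 sort genes passed the rule at both stages. Of the dissociation stress genes, 2 of 14 fell, Hspa1a (−4.45 and −4.74, uncertain because of its near-identical copy Hspa1b) and Ier3 (−2.55 and −4.02).

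Outside the lists, the largest rises at both stages were in Hist1h2ap (6.54 and 6.07), Itm2a (5.46 and 5.20), Cav1, the caveolin of fat cell membranes (5.52 and 3.66), Pla2g16 (6.01 and 3.42), Hist1h2ae (3.69 and 3.42) and Hmmr (5.27 and 3.27). The histone genes have near-identical copies and are uncertain. The largest falls were in Pitx1 (−3.48 and −6.80) and Barx1 (−2.78 and −5.19), transcription factors of limb and jaw mesenchyme, Pappa (−2.68 and −4.22), Fez1 (−2.50 and −3.23), Egfl6 (−2.47 and −4.01), Sh3gl3 (−2.45 and −4.58), Hs3st1 (−2.36 and −3.94) and Ier5l (−2.27 and −2.79). The unnamed cluster 7, led by Hoxd11 and Hoxd13, held 247 and 24 cells in the PDGFRa and 0 and 2 in the Ebf2-GFP libraries. Whether the libraries held the same body regions was not tested. With 4000 variable genes the values of Pitx1 (1.27, with a count of 0 set to 3) and Barx1 (4.05) at E14.5 and of Hmmr (−0.57) at E15.5 turned. That of Pappa at E15.5 turned with at least 2000 genes and at most 5% mitochondrial UMIs (0.026) and with each library clustered on its own (0.84). Other classes shared some of these differences: 16 of the 159 rises and 18 of the 221 falls were also 2-fold in at least 50% of the other 9 classes with enough UMIs, among them Itm2a, Car3, Col15a1, Cav1, Hist1h2ap, Hist1h2ae, Hspa1a, Ier3 and Ier5l.

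Within cluster 16 alone, 67 genes rose and 47 fell at both stages, and the gene groups differed from those of the whole class. The extracellular matrix genes were higher in Ebf2-GFP cells, at medians of 0.81 [0.75, 0.93] and 0.75 [0.70, 0.84], with 4 of 19 past the rule at both stages. The dissociation stress genes stood at 0.59 [0.51, 0.68] and 0.69 [0.62, 0.76], with 3 of 14 higher, such as Zfp36 (2.43 and 2.01), and 2 lower, Hspa1a (−3.92 and −3.32) and Ier3 (−2.03 and −2.65). Lipid storage genes stood at 0.67 and 0.18, thermogenic genes at 0.32 and −0.05 and cell cycle genes at 0.44 and −0.44. Retinoic acid (−0.83 and −0.62) and BMP (−0.65 and −0.71) genes were again lower, with 1 of 3 and 1 of 7 past the rule at both stages. Genes past the rule at both stages in this cluster included Itm2a (5.93 and 6.81), Aspn (3.21 and 2.69), Car3 (5.87 and 1.88), Fndc1 (1.88 and 2.57), Pitx1 (−2.91 and −5.64), Barx1 (−2.18 and −3.07), Egfl6 (−1.92 and −2.47), Igfbp2 (−1.85 and −2.68) and Crabp2 (−1.76 and −2.92). Gstp1 (3.57 and 2.40) has near-identical copies and is uncertain.

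The step from E14.5 to E15.5 asks how adipogenic-like cells change with age, E13.5 having too few of them (13 cells) for a comparison of genes. In the PDGFRa sort, where cluster 16 held 125 of 125 and 214 of 228 cells, 65 genes rose and 33 fell. In the Ebf2-GFP sort, where the class went from mostly cluster 16 to mostly cluster 28, 278 rose and 581 fell. Only 13 genes rose and 13 fell in both, and with at least 2000 genes and at most 5% mitochondrial UMIs 18 rose and 1 fell. The median of all genes was −0.21 in the Ebf2-GFP sort.

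Rises in both sorts, PDGFRa first, included Car3 (6.88 and 2.26), Cebpb, an early adipogenic transcription factor (1.22 and 1.40), Apoe (1.31 and 1.27), Cavin1 (1.35 and 1.13), Tspo (1.04 and 2.84), Mcrip2 (1.75 and 1.51), Crip2 (1.21 and 1.62), Ptges2 (1.09 and 1.32), and the cell cycle genes Mki67 (1.66 and 1.15), Top2a (1.39 and 1.10), Rrm2 (1.36 and 1.32) and Ube2c (1.11 and 1.16). Falls included the WNT modulator Sfrp2 (−1.14 and −2.75), Cd24a, a surface marker of adipocyte progenitors (−1.08 and −1.92), Crabp2 (−1.09 and −3.66), Igfbp3 (−1.37 and −1.89), Gap43 (−1.51 and −1.46), Egfl6 (−1.29 and −2.83), C1qtnf4 (−1.20 and −2.55), Phf21a (−1.20 and −1.52), Fam69b (−1.12 and −1.49), Vcam1 (−1.08 and −1.85), Itgb5 (−1.07 and −1.43) and Ccdc112 (−1.01 and −2.27). Thermogenic genes stood at a median of 0.49 [0.24, 0.80] (percentile 98.2, none of 3 past the rule) in the PDGFRa sort and 1.72 [1.61, 1.92] (7 of 13 higher) in the Ebf2-GFP sort. In cluster 16 alone the PDGFRa value was 0.34 [−0.019, 0.59]. Lipid storage genes stood at 0.54 [0.24, 0.96] (3 of 9 higher) and 1.34 [1.17, 1.51] (11 of 20 higher). Extracellular matrix genes stood at 0.47 [0.38, 0.52] in the PDGFRa and −1.11 [−1.15, −1.06] in the Ebf2-GFP sort. With cells thinned to 5000 UMIs, 11 genes passed in both sorts, 3 higher and 8 lower. In cluster 16 alone 15 did, 12 higher, such as Igfbp6 (1.91 and 1.44) and Nupr1 (1.51 and 1.18), and 3 lower. Of the genes named for the class, only Car3, Egfl6 and C1qtnf4 were among these 15. With at least 2000 genes and at most 5% mitochondrial UMIs per cell, the PDGFRa values of Mki67 (−0.28), Top2a (−0.67), Rrm2 (−0.19), Ube2c (−0.61), Igfbp3 (0.07) and Vcam1 (0.13) turned, as did those of Ube2c (−0.26) and Vcam1 (0.18) with 4000 variable genes.

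**Figure D3:**
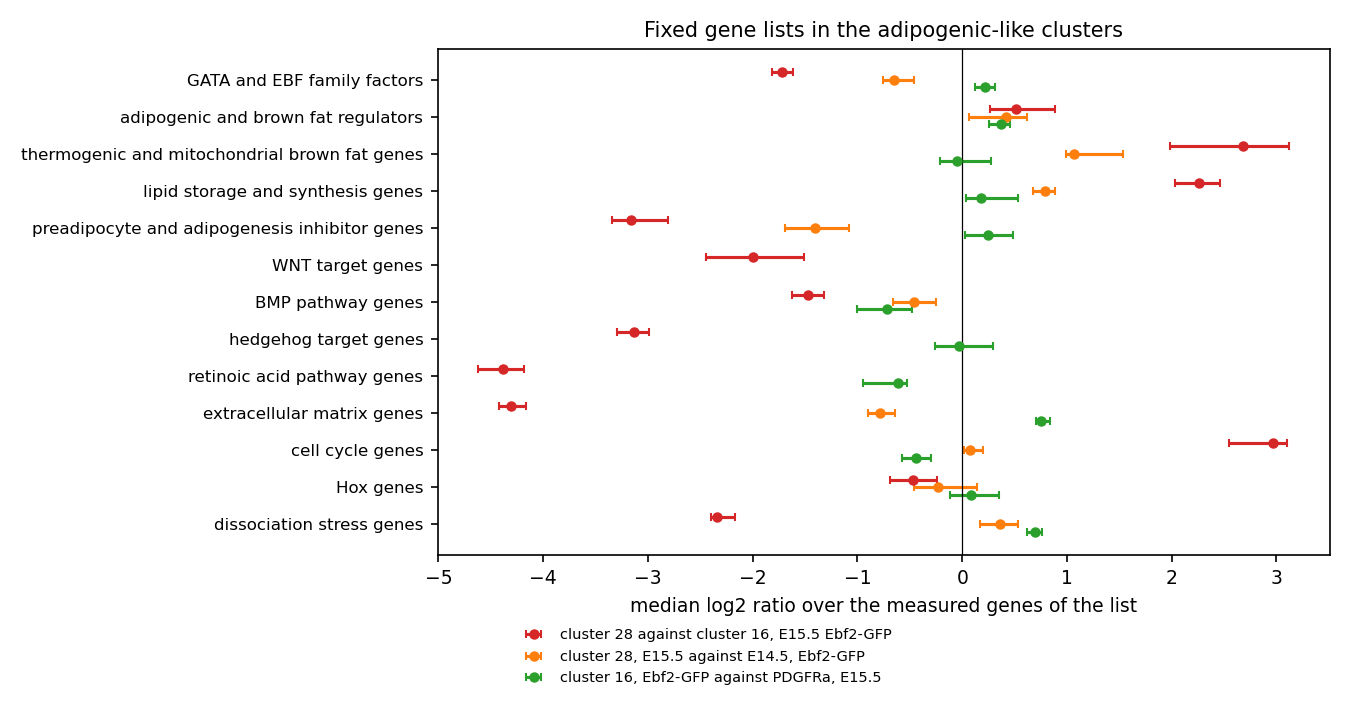
Median log2 ratio of each fixed gene list (points) with 95% intervals from redrawn counts (bars), for cluster 28 against cluster 16 in the E15.5 Ebf2-GFP library, for E15.5 against E14.5 in cluster 28, and for the sorts at E15.5 in cluster 16. In the first of these the extracellular matrix genes stand at −4.30 and the thermogenic genes at 2.68.

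Cluster 28 itself changed from E14.5 to E15.5 in the Ebf2-GFP sort, where 158 genes rose and 147 fell. The thermogenic and mitochondrial genes were higher, with a median of 1.07 [0.99, 1.54] (percentile 99.99) and 4 of 13 past the rule. They included Cox7a1, a subunit of cytochrome c oxidase (2.82 to 125 CPM, 5.47 [4.35, 6.92]), and Cidea, a lipid droplet protein of brown fat (1.41 to 61.6 CPM, 5.45 [3.90, 7.73]). Ucp1, the uncoupling protein of brown fat heat production, stood at 3.28 CPM (7 UMIs) and 6.29 CPM (111 UMIs), and at no more than 1.04 CPM in any other cluster over the 7 libraries. Of 19 lipid storage genes 8 rose, such as Retn (2.05), Pnpla2, the main triglyceride lipase (2.04), and Gpd1 (1.66), with a median of 0.79 [0.68, 0.88]. Regulators had 4 of 19 higher, with Rxrg (1.45) and Mlxipl (1.26), and Lhx8 lower (−1.97). Of 7 preadipocyte genes 3 fell: Dlk1, which restrains adipogenesis (872 to 330 CPM, −1.40), F3 (−1.83) and Sfrp2 (−1.98). Matrix genes stood at −0.78 [−0.90, −0.64], with Fbn2 (−1.74), Loxl1 (−1.36) and Col5a1 (−1.01) lower.

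Other large rises in cluster 28 were Coq8a, of coenzyme Q synthesis (5.51), Thrsp (4.93) and Chchd10 (3.01), both leading genes of the cluster, Sncg (4.81), S100a1 (4.01), Cfd, the adipokine adipsin (3.73), Gpx8 (3.59), Ntrk3 (3.41), Tst (2.73) and the cell cycle inhibitor Cdkn1a (2.90). Large falls were Ptn (−3.13) and Mdk (−3.06), related growth factors, Cpxm1 (−3.01), Dbn1 (−2.59), Aspn (−2.45), Iigp1 (−2.15), Cited4 (−2.08), Mmp2 (−2.07), Frmd6 (−1.99) and Ckap4 (−1.93). Of 19 cell cycle genes, Cdkn1a rose and Cdkn1c fell (−1.25), with a median of 0.08.

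Against cluster 16 of the same library, cluster 28 had higher thermogenic genes (2.68 [1.98, 3.12] at E15.5, 8 of 13) and lipid storage genes (2.26 [2.03, 2.46], 13 of 20). Cell cycle genes were also higher (2.96, 16 of 19), Mki67 standing at 223 against 27.3 CPM. The unnamed cluster 18, with 4 of 10 fibroblast and 3 of 10 adipogenic markers, was in neither sum and had Mki67 at 462.6 and Pparg at 38.6 CPM over the 7 libraries. Lower were the retinoic acid genes (−4.38, 2 of 3), extracellular matrix genes (−4.30 [−4.42, −4.16], 20 of 20), preadipocyte genes (−3.17, 8 of 9), dissociation stress genes (−2.34, 11 of 13) and hedgehog target genes (−3.13, 3 of 3). Single examples were Rxrg (4.97), Ppargc1a (3.96), Pnpla2 (4.34), Fn1 (−5.29), Col1a2 (−5.19) and Dlk1 (−3.32), with Ebf2 at 0.06 and Ebf3 at −1.99. At E14.5 the medians went the same way, at 0.97, 2.26, 2.17, −2.85, −3.30, −1.33, −2.01 and −2.15. The GATA and EBF family factors stood at −1.72 at E15.5, with 3 of 4 lower. Cells of cluster 28 were deeper, with a median of 26128 against 10088 UMIs at E15.5, and the median of all genes was −0.16.

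Fibroblast-like cells of the PDGFRa sort had higher matrix and immediate early genes at E15.5 than at E13.5. By the rule and with the E14.5 level in between, which the list counts also needed, 362 genes rose and 119 fell. Of the 20 extracellular matrix genes 16 rose and none fell, with a median of 1.60 [1.56, 1.65] (percentile 100), among them the collagen Col6a3 (2.72), Thbs2 (2.49), Tnxb (5.71) and Mfap5 (3.87). Of the 15 dissociation stress genes 8 rose, with a median of 1.21 [1.11, 1.31], such as Junb (2.62), Egr1 (61.1 to 346.5 CPM) and Atf3 (2.25). Ebf2 went from 14.9 to 93.0 CPM (2.64). The class was mostly cluster 3 at E13.5 (1398 of 1460 cells) and was spread over clusters 3, 4 and 17 at E15.5 (556, 935 and 521 of 2012 cells).

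The other lists had fewer members past the rule in these cells. The early adipogenic factors Cebpd (2.62) and Cebpb (2.30) rose and Lhx8 fell (−1.75), of 19 regulators. The WNT target Lef1 fell (−1.28) and Wif1 rose (1.04), of 13. Of 8 retinoic acid genes Stra6 (−2.07), Aldh1a2 (−1.36) and Crabp2 (−1.03) fell and Aldh1a3 rose (1.49). Icam1, of the preadipocyte list, rose (2.96). Hedgehog target genes (0.86 [0.69, 1.01]) and BMP genes (−0.51 [−0.56, −0.40]) had no member past the rule, nor had the thermogenic (−0.18) and lipid storage (−0.29) genes. Hox genes stood at 0.34 and cell cycle genes at 0.41, with 4 of 19 higher, such as Top2a (1.31) and Cdkn1a (1.83). The direction of both medians depended on the settings: that of the Hox genes was negative under 5 alternatives, such as Leiden resolution 2.0 (−0.13) and 4000 variable genes (−0.27), and that of the cell cycle genes under 4, such as Leiden resolution 0.5 (−0.34).

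The largest rises were Clec3b (7.45), Sfrp5 (6.88, with 0 UMIs set to 3), Abca8a (4.61), Itih5 (4.58), S100a16 (4.41), Tppp3 (4.22), Nupr1 (4.09), Abca9 (4.05), Fam129a (3.98) and Rbp4 (3.94). Clec3b, Tnxb and Mfap5 are leading genes of cluster 4 and Sfrp5 of cluster 17, clusters nearly absent at E13.5. The largest falls were Pantr1 (−3.44), Cxadr (−2.89), Veph1 (−2.79), Dlx5 (−2.70), Pou3f3 (−2.69), Hmga2, a fetal chromatin protein (−2.64, 527.7 to 84.6 CPM), Barx1 (−2.51), Dlx6 (−2.42), Sept3 (−2.41), Zcchc18 (−2.38), Otor (−2.37) and Fblim1 (−2.25). Of these changes, 81 of the 362 rises and 26 of the 119 falls were also 2-fold in at least 50% of 7 other classes, among them Junb, Egr1, Atf3, Col6a3, Thbs2, Mfap5, Itih5, Abca9, Hmga2 and Barx1. At resolution 2.0 an unnamed cluster led by genes such as Barx1, Dlx6 and Dlx5 held 764 cells at E13.5 and 299 at E15.5 in the PDGFRa sort. Whether the libraries of these stages held the same body regions was not tested.

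Within cluster 3 alone, 235 genes rose and 69 fell. Matrix genes (1.57 [1.52, 1.60], 14 of 19 higher) and stress genes (1.24 [1.06, 1.35], 8 of 15) were close to the whole class, with Eln, the elastin gene (3.15), Mfap5 (3.09), Matn2 (3.19), Abi3bp (2.86), Igfbp7 (2.81), Cebpb (2.41) and Egr1 (2.55) as examples. The Hox genes turned to −1.36, 4 of 12 lower, with Hoxc5 (−2.88) and Hoxc4 (−1.71), and the cell cycle genes to −0.81, 4 of 17 lower, with Birc5 (−1.55). Ebf2 was 14.7 CPM at E13.5 and 14.3 CPM at E15.5 in this cluster (−0.04 [−0.44, 0.35]). Summed over the 7 libraries, Ebf2 was 151 CPM in cluster 4 and 19.1 CPM in cluster 3. Hmga2 (−1.95), Six2 (−2.04) and Lix1 (−1.83) were among the other falls.

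Dermomyotome-like cells, named by Pax3, Pax7, En1 and other somite genes, were found only at the finer Leiden resolution of 2.0, a step chosen after seeing the data. They made up 4.17% of cells at E11.5 (375 cells), 1.09% at E12.5 (85 cells) and 0.0704% at E13.5 (6 cells). Gata6 was low in them, 2.21 CPM at E11.5 (13 UMIs), against 3.96 CPM in fibroblast-like cells (log2 −0.84 [−1.78, −0.02]), 2.24 CPM in myogenic-like cells and 17.6 CPM in sclerotome-like cells (−2.99) of that resolution. At E12.5 it stood at 1.51 CPM, from 2 UMIs, against 9.68 CPM in fibroblast-like cells (−2.68 [−5.75, −0.77]). These fibroblast-like cells were not the same at both stages: at E11.5 nearly all were of cluster 5 of that resolution (2003 cells), led by genes such as Barx1, Alx1 and Lhx8, and at E12.5 of clusters 5 and 9 (199 and 406 cells). The E11.5 ratio to fibroblast-like cells was −4.50 with each library clustered on its own, but its interval included 0 with median-of-ratios scaling (−0.74 [−1.69, 0.08]), cells thinned to 5000 UMIs (−1.40 [−3.72, 0.24]) and at most 20% mitochondrial UMIs (−0.69 [−1.53, 0.06]).

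From E11.5 to E12.5, 39 genes rose and 29 fell in dermomyotome-like cells. Rises were the cell division kinesin Kif14 (2.41), Gria2 (2.21), Cited1 (1.88), the ligand Bmp4 (1.87), the WNT modulator Dkk2 (1.69), Alcam (1.63), the posterior Hox genes Hoxa10 (1.61) and Hoxd11 (1.41), Cdo1 (1.53), Snai2 (1.52), Myl9 (1.45) and Osr1 (1.41). Falls were Prtg (−2.54), Igdcc3 (−2.35), Dqx1 (−2.03), Fignl2 (27.3 to 6.81 CPM), Wnt16 (−1.84), the somite factor Uncx (−1.80), Itga6 (−1.78), Stam2 (−1.64), Hoxa4 (−1.40), Plch1 (−1.36), Ntm (−1.32), and Hist1h2ak (−2.19), which is uncertain because of near-identical copies. Matrix genes stood at 0.59 [0.43, 0.74], with Col1a1 (1.17) the 1 of 8 past the rule. BMP genes stood at 0.34 [0.23, 0.49], Bmp4 rising and Grem1 falling (−1.18) of 9. Of 18 Hox genes 3 rose, Hoxc8 (1.22) included, and 2 fell. Dlk1 fell (−1.15), Cdkn1c rose (1.13), and no GATA or EBF factor passed. Of these changes, 12 of 39 rises and 7 of 29 falls were 2-fold in at least 50% of 7 other classes. Among these rises were Gria2, Dkk2, Hoxa10, Hoxd11, Cdo1, Osr1 and Col1a1, and among the falls Prtg, Igdcc3, Wnt16, Fignl2 and Hist1h2ak. With cells thinned to 5000 UMIs 28 genes passed, 10 higher and 18 lower. With each library clustered on its own 551 did, 323 higher and 228 lower, and there Kif14 (−4.61) and Ntm (0.57) turned.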

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

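Of the tests in this part, those of Pdgfra between clusters 16 and 28 and of free Gata6 RNA were chosen after the result was seen, as were the 20% mitochondrial limit, the values for single clusters, and the thinning of cells for eGFP. The others were fixed before their result was seen.

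Several gene lists and genes in adipogenic-like cells went opposite ways at the matched stages, Ebf2-GFP over PDGFRa. Log2 values at E14.5 and E15.5 were 0.30 and −0.85 for GATA and EBF family factors, 0.46 and −1.11 for extracellular matrix genes, 0.16 and −0.56 for dissociation stress genes, 0.40 and −0.90 for Gata6, and 0.20 and −0.81 for Ebf1. From E14.5 to E15.5, the PDGFRa and Ebf2-GFP sorts went opposite ways in extracellular matrix genes (0.47 and −1.11) and dissociation stress genes (0.32 and −0.75). In each of these, the E15.5 Ebf2-GFP class was mostly cluster 28 (669 of 1093 cells). The opposition between stages was gone for the 3 lists with at least 2000 genes and at most 5% mitochondrial UMIs, where the E15.5 values were 0.14, 0.91 and 0.51, and in cluster 16 on its own, where they were 0.22, 0.75 and 0.69, and the E14.5 value of the GATA and EBF factors was −0.036 with 4000 variable genes.

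In fibroblast-like cells the hedgehog target genes stood at 0.26 at E14.5 and −0.24 at E15.5, Ebf2-GFP over PDGFRa. From E14.5 to E15.5, the PDGFRa and Ebf2-GFP sorts differed in direction for hedgehog target genes (0.46 and −0.067), lipid storage and synthesis genes (−0.12 and 0.26), Ebf3 (0.38 and −0.15) and Pdgfra (0.12 and −0.10). The cluster mix differed here as well, cluster 4 holding 172 of 1901 and 935 of 2012 of these cells in the PDGFRa and 1565 of 2186 and 1748 of 2040 in the Ebf2-GFP libraries. None of the differences in this or the preceding paragraph was itself tested, since each side is 1 library.

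Signal was also present in data outside the comparisons of genes and lists. The eGFP feature had 3578 UMIs in the E14.5 and 3406 UMIs in the E15.5 Ebf2-GFP library, above the 3 that a count of 0 allows. The E10.5 library, without gene names, had a median of 14796 UMIs per barcode.

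The first pattern weighed is a set of 3 neural-like clusters, led by genes such as Lhx9 and Neurod6, with 994 of 9204 and 892 of 7231 cells in the E14.5 and E15.5 Ebf2-GFP libraries and none in the PDGFRa libraries of those stages. Hox genes, silent in the front of the neural tube, stood at 12.3 CPM there against 2092 CPM in the other neural-like clusters, or 0.587%, which is consistent with brain tissue in the material, although the labels say that heads were removed. An eGFP UMI was found in 13.9% of these cells, 44.3% of adipogenic-like and 1.02% of myogenic-like cells (median depths 5285, 14880.5 and 11739 UMIs), so the limit fixed beforehand for a gate that takes neurons carrying eGFP, 50% of the adipogenic-like share, was missed over both libraries and at E15.5 (8.74% and 47.7%), while the E14.5 value (18.5% [16.1, 21.1], and 36.9%) lay at it within counting error. With cells thinned to 5000 UMIs, a step chosen afterwards, it was met (16.7%, 22.2% and 0.384%, leaving out 811, 87 and 37 shallower cells), so a gate of this kind stays open. The 3 clusters differed in Ebf2 itself over the 7 libraries, at 203 CPM in cluster 22, led by Lhx9, and 3.68 and 3.29 CPM in clusters 33 and 37. By Ebf2 RNA the gate stays open for cluster 22, and clusters 33 and 37 give it no such support. The eGFP share was not split among the 3 clusters. With the clusters pooled, the tests exclude neither explanation, and no biological explanation was tested.

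The second pattern is the higher share of adipogenic-like cells in the Ebf2-GFP libraries. An unequal effect of the limit on mitochondrial UMIs stays open for cells above 20% and for E14.5, which the test did not cover. At 20% the fold at E15.5 was 115.6 rather than under 1.5, the value set for this explanation. That run drew the class anew, from 1093 to 1766 cells in the Ebf2-GFP and from 228 to 14 in the PDGFRa library. The fold thus cannot tell how many cells of the same class the main limit removed. All cells kept at E15.5 went from 7231 to 8725 in the Ebf2-GFP and from 7837 to 7994 in the PDGFRa library. A PDGFRa gate that leaves out cells with little Pdgfra stays open for cluster 28, where Pdgfra was 3.05% of its level in cluster 16, but cluster 16, at 128 CPM, was itself 3.28-fold and 2.15-fold higher in share. Embryos further in development than the label also stay open: on a scale from 0 (E13.5 PDGFRa) to 1 (E15.5 PDGFRa), the E14.5 Ebf2-GFP library stood past the E14.5 PDGFRa library by a median of 0.378, with 1.03 against 0.610 in endothelial-like, 0.977 against 0.467 in myogenic-like, 0.854 against 0.514 in Schwann and neural crest-like and 0.755 against 0.620 in macrophage and leukocyte-like cells. Genotype, Cell Ranger version and possibly sequencer and enzyme differ along with the sort and might shift these positions too, and the reporter genotype stays open as an untested biological difference.

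The third pattern is the higher Gata6 in adipogenic-like than in fibroblast-like cells. Free RNA is argued against, since the share of neural-like cells with a Gata6 UMI was at most 1.42% of that of adipogenic-like cells over 4 libraries, although the upper limit in the E15.5 PDGFRa library, with 71 neural-like cells, was 10.3%. Cells caught with mesothelial or Gata4-expressing body wall cells are argued against as well, for the 4 libraries summed. Gata4 (9 UMIs) was 0.597% of Gata6 (1508 UMIs) in adipogenic-like cells and 23.5% in the Gata6-rich clusters 35 and 40, a ratio of 2.54%. The sum was not split by library, so it does not speak for the E14.5 PDGFRa library alone. A ratio to Gata4 also cannot detect Gata6-rich cells with little Gata4. What stays open is the choice of cells and the drawing of the clusters, since the E14.5 PDGFRa ratio was −0.12 with at least 2000 genes and at most 5% mitochondrial UMIs. At resolution 2.0 only 38 cells of that library were adipogenic-like, and Gata6 was a leading gene of the mural-like cluster 19. A difference between the cell classes in the tissue may then remain, as a hypothesis that these data alone cannot settle.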

How the results depend on the processing

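The 20% mitochondrial limit, clusters 16, 28 and 3 on their own, and the removal of genes changed in other classes were chosen after the data were seen; the other alternatives were planned. Over 11 main results there were 79 values, of which 44 stayed within the counting interval or within 1.5-fold for counts, 34 moved and 1 changed sign. Over 176 single genes and lists there were 1222 values, of which 657 stayed, 505 moved and 60, in 33 results, changed sign. Unless stated, values are log2 ratios and the cause was not tested.

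The 3 ratios of adipogenic-like share kept their sign under all 9 alternatives each, at 1.19 to 6.72 and 1.10 to 6.85 between sorts at E14.5 and E15.5, and 0.77 to 5.72 from E13.5 to E15.5. The thermogenic median from E14.5 to E15.5 in the PDGFRa sort stayed at 0.34 to 0.50 over 4 alternatives. The interval of the lowest, cluster 16 on its own, included 0 ([−0.019, 0.59]). Median-of-ratios scaling and the limit of 30 UMIs moved no main result and turned none of the values they gave.

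Without removal of doublets, the adipogenic-like share ratio between sorts was 2.74 at E14.5 and 3.08 at E15.5, and 5.35 from E13.5 to E15.5. Gata6 in adipogenic-like over fibroblast-like cells of the E15.5 Ebf2-GFP library was −0.39, and the sort genes between sorts at E15.5 in adipogenic-like cells stood at −0.20.

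With at least 2000 genes and at most 5% mitochondrial UMIs, the share ratios were 1.19, 1.21 and 0.77 in that order. Gata6 was −0.12 in the E14.5 PDGFRa and −0.092 in the E15.5 Ebf2-GFP library. Between sorts in adipogenic-like cells, 114 genes passed at both stages, and thermogenic medians were 0.25 at E14.5 and −0.10 at E15.5. At E15.5 the medians were 0.14 for GATA and EBF factors, 0.24 for preadipocyte genes, 0.37 for hedgehog targets, 0.91 for matrix genes and 0.51 for stress genes. Pappa was 0.026, and at E14.5 cell cycle genes were −0.25 and Ccnb1 −0.18. From E14.5 to E15.5 in the PDGFRa sort, Rrm2 was −0.19, Mki67 −0.28, Ube2c −0.61, Top2a −0.67, Igfbp3 0.070 and Vcam1 0.13. Thermogenic genes in fibroblast-like cells from E13.5 to E15.5 stood at 0.0047.

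At Leiden resolution 0.5 the share ratios between sorts were 6.72 and 4.25, Gata6 in the E15.5 Ebf2-GFP library was −0.48, and cell cycle genes in fibroblast-like cells from E13.5 to E15.5 stood at −0.34. At Leiden resolution 2.0 the share ratios were 3.24 and 3.32, Hox genes in fibroblast-like cells stood at −0.13 and sort genes in adipogenic-like cells at E15.5 at −0.34.

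With 4000 variable genes the share ratio was 3.62 between sorts at E14.5 and 5.65 from E13.5 to E15.5, and Gata6 in the E15.5 Ebf2-GFP library was −0.011. Between sorts in adipogenic-like cells 184 genes passed at both stages, GATA and EBF factors stood at −0.036 at E14.5, and at E15.5 cell cycle genes at −0.20, sort genes at −0.27 and Hmmr at −0.57. At E14.5 Pitx1 was at least 1.27 and Barx1 4.05. From E14.5 to E15.5 in the PDGFRa sort Ube2c was −0.26 and Vcam1 0.18, and Hox genes in fibroblast-like cells from E13.5 stood at −0.27.

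With each library clustered on its own, the share ratio was at least 6.65 between sorts at E14.5 and at least 5.72 from E13.5 to E15.5. Gata6 was −0.25 in the E14.5 and −0.13 in the E15.5 Ebf2-GFP library, and −4.50 in dermomyotome-like over fibroblast-like cells at E11.5. In dermomyotome-like cells 551 genes passed, with Kif14 at −4.61 and Ntm at 0.57. In fibroblast-like cells from E13.5 to E15.5 cell cycle genes stood at −0.49 and Hox genes at −0.29, and Pappa between sorts at E15.5 at 0.84.

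With cells thinned to 5000 UMIs, which leaves fewer UMIs and cells for the rule, 28 genes passed in dermomyotome-like cells, 144 between sorts at both stages and 11 from E14.5 to E15.5 in both sorts. In adipogenic-like cells between sorts, preadipocyte genes stood at 0.30 at E14.5 and Hox genes at 0.78 at E15.5.

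With at most 20% mitochondrial UMIs, the share ratios were at least 5.10 at E14.5, 6.85 at E15.5 and at least 2.35 from E13.5 to E15.5. Gata6 was −0.046 in the E14.5 and −1.03 in the E15.5 Ebf2-GFP library, and in fibroblast-like cells cell cycle genes stood at −0.85 and Hox genes at −0.051.

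In cluster 16 on its own, the share ratios between sorts were 1.71 and 1.10, and thermogenic medians 0.32 and −0.054. Between sorts 114 genes passed at both stages, and 15 from E14.5 to E15.5. Preadipocyte genes stood at 0.00094 at E14.5 and 0.25 at E15.5, and at E15.5 GATA and EBF factors at 0.22, matrix genes at 0.75, cell cycle genes at −0.44, Hox genes at 0.083, stress genes at 0.69, Hist1h2ae at −0.69 and Ccnb1 at −0.018. In cluster 28 on its own, the share ratios were 5.06 (lower limit 4.73), 5.69 and 2.34 (lower limit 1.85), the first and last with a count of 0 set to 3. Gata6 in the E15.5 Ebf2-GFP library was −0.10 in this cluster. In cluster 3 on its own, 304 genes passed from E13.5 to E15.5, with Ebf2 at −0.043, cell cycle genes at −0.81 and Hox genes at −1.36.

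Alternatives gave no value where a class held fewer than 50 cells in a library. So counts of genes in adipogenic-like cells had none without removal of doublets, at both other resolutions, or with each library on its own, and Gata6 at E14.5 in the PDGFRa sort had none there either. Gata6 in dermomyotome-like cells at E11.5 had none without removal of doublets, under the stricter filter, at resolution 0.5 and with 4000 variable genes. Depth limits these results too: a gene needed 100 UMIs over both sums, and the adipogenic-like cells of the E14.5 PDGFRa library were 125.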

Other observations

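Fibroblast-like cells also differed between the sorts, a comparison chosen after the data were seen. At both E14.5 and E15.5, 153 genes were higher and 119 lower in the Ebf2-GFP than in the PDGFRa library. The cluster mix differed too: cluster 4 held 172 of 1901 and 935 of 2012 of these cells in the PDGFRa and 1565 of 2186 and 1748 of 2040 in the Ebf2-GFP libraries, at E14.5 and E15.5. Extracellular matrix genes stood at medians of 1.36 [1.32, 1.41] and 0.96 [0.93, 0.98], with 7 of 20 past the rule at both stages, such as Tnxb (4.05 and 2.85) and Mfap5 (3.01 and 2.47), both leading genes of the fibroblast-like cluster 4. WNT target genes stood at −1.80 and −1.51, with 5 of 13 lower, such as Lef1 (−2.15 and −2.37) and Axin2 (−1.92 and −2.01). BMP pathway genes stood at −0.86 and −1.01, with 4 of 14 lower, and dissociation stress genes at 0.62 and 0.81, with 6 of 15 higher and 2 lower. Among the genes with the largest differences were Itm2a (8.78 and 8.16) and Clec3b (5.26 and 2.69), which were higher, and Irx5 (−2.77 and −2.71), Irx3 (−2.73 and −2.69) and Msx1 (−2.90 and −2.61), which were lower.

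From E13.5 to E15.5 in the PDGFRa sort, genes past the rule with the E14.5 level in between were also counted in other classes. They were 506 in neural-like, 352 in chondrocyte-like, 205 in macrophage and leukocyte-like and 192 in Schwann and neural crest-like cells. In myogenic-like, mural-like and endothelial-like cells they were 191, 137 and 76. The neural-like class changed its clusters, with 404 and 201 of 751 cells in clusters 15 and 20 at E13.5, and 32 of 71 in cluster 39 and 25 in cluster 15 at E15.5. In Schwann and neural crest-like cells C1ql3 (4.32) and Abca8a (4.27) had the largest rises and Gpnmb (−3.26) the largest fall. In myogenic-like cells these were Crip1 (4.05), Col15a1 (3.88) and, falling, Fst (−4.69). None of the 26 genes that changed from E14.5 to E15.5 in adipogenic-like cells of both sorts changed 2-fold the same way in at least 50% of the other classes, 11 of which could be compared.

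At E11.5, dermomyotome-like cells had higher Hox genes than fibroblast-like cells, nearly all of 1 cluster (2003 cells), with a median of 2.68 and 14 of 21 higher, among them Hoxc5 (4.15) and Hoxc8 (3.76). Zic1 (4.06) and Lrig1 (3.04) were also higher and Lhx8 (−4.19) lower.

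The test of the E10.5 matrix was fixed before its result was seen. Its row sums might follow the gene order of the E14.5 Ebf2-GFP library: across 31054 rows, which are not independent replicates, Spearman's rho was 0.954 in the unshifted order. A shift by 1 row gave 0.373, above the limit of 0.3 set for every shift, so the order could not be settled and no gene of this library is reported.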
